A study of Homo sapiens with 5 samples.

How the data were processed

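Total RNA of infected and uninfected human foreskin fibroblasts was measured on 5 two-colour whole human genome oligonucleotide arrays. Per the labels' protocols, RNA was primed with oligo-dT, copied into double-stranded cDNA, amplified as antisense RNA and labelled chemically, with uninfected RNA of 0 h in Cy3 and infected RNA of 4, 16, 48, 72 or 120 h in Cy5. Each time point had 1 array, so groups hold 1 sample each. The deposited value table holds log ratios, which were taken as log2 ratios; base 10 was excluded because the largest value would exceed a scanner's range, and a natural log was not. The software, background correction, normalization and filters behind these deposited log2 values are not given in the sources used here. The direction was taken as likely infected over uninfected from the titles and the series design, and no pair of arrays correlated below 0. Spot signals were not analysed here, so no filter on dim probes was possible and the number of arrays limits the precision.

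The table has 41000 probes. A platform annotation gave 29332 probes 1 gene symbol, 0 several and 11668 none, and 29259 were matched by gene ID to a reference gene table, whose symbols were used. Probes of a gene were averaged on the log2 scale, which gave 18423 genes on at least 1 array and 17074 on all 5, of which 9417 had 1 probe. Of the named genes, DSC3, FADS2 and SPRR1A had probes whose means differed in sign. All 5 columns of values were used. The 4 and 16 h arrays lacked the same 4603 probes. On each array up to 224 probes shared 1 identical value, for which the sources give no reason.

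Before the data were examined, 41 gene lists (pathways, complexes and cell type markers), the tests, the rule for named genes and most alternatives were fixed. Genes at least 2-fold higher or lower were counted on each array by size alone (log2 ratio of 1 or more), with no p-value. A time trend was the slope on log2 hours and an average change the mean over arrays against 0, both by limma 3.58.1 in R 4.3.3 with eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The slope has 3 residual degrees of freedom and the mean 4, both from the spread between time points. The mean takes the uninfected RNA as 1 control sample and leaves out its spread. Lists were tested with camera at a preset correlation of 0.01, with estimated correlation and fry as alternatives, and adjusted over the 41 lists. A list's median on an array was placed among 10000 random gene lists of its size, which could not be matched on expression because the table holds none.

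Named genes have 1 symbol and a value on all 5 arrays: 10 per direction with the largest mean among genes of the same sign on each array, the 4 highest and 4 lowest at each time, the steepest among those past the trend threshold (0 passed), and the 4 members with the largest mean in size of each list described. XIST and Y-linked genes were left out. Members of the lists without a listed probe were not analysed here. The fits were tested on simulated normal noise with the eBayes spread of the 17074 real genes and changes put into randomly picked genes. Slopes of 0.5 were recovered for 96% and of 1 for 100% of 100 genes each, with 20 false calls. Means of 1 and 2 were recovered for 98% and 100% with 10 false calls. These shares do not hold for real genes with more scatter. IFIT1, with a slope of 1.04 (standard error 0.246), did not pass the trend test by limma (adjusted p = 0.858). The simulated noise was independent between arrays and had no shared control. The false calls of the mean therefore leave out noise of the control that all real arrays share.

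Alternatives were array centring on the median or the densest value, scaling to one median absolute deviation, quantile normalization, the median of probes, robust eBayes, filters on size and probe number, other codings of time, leaving out each array, a block for the early and late arrays, and the late arrays alone. Overlaps and covariances of arrays were set beside values simulated or computed for unchanged RNAs that share 1 control, with control and infected noise of equal size. Gene neighbours came from the order of gene starts on each chromosome in the reference table, and its coordinates were used only for that order. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.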

Results

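The series followed the response of human cells to Encephalitozoon cuniculi, a microsporidian, which is a fungus-related parasite that lives inside host cells and spreads as spores. The host cells were human foreskin fibroblasts, an established line, and the spores had been produced in MDCK cells, a dog kidney epithelial line. RNA of infected cells was taken at 4, 16, 48, 72 and 120 h and hybridised against RNA of uninfected cells of 0 h, with 1 array per time point. Infected RNA carried Cy5 and uninfected RNA Cy3 on each of the 5 arrays. No time point was replicated, no dyes were swapped and no uninfected cells of a later age were measured, so a difference at 1 time point has no replicate check. Values are log2 ratios per gene; the direction, infected over uninfected at 0 h, is likely from the titles and the design text but is not stated for the value table, and a natural log is not excluded as its base. How the table was centred is not known either. Spot signals were not analysed here, so dim probes could not be told from bright ones.

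The arrays differed in the shape of their distributions, which bears on every list below. The median over probes was 0.11 at 4 h, 0.14 at 16 h, -0.05 at 48 h, 0.05 at 72 h and 0.07 at 120 h. The densest value over genes was 0.26, 0.19, -0.08, 0.12 and 0.19 in the same order, above the median on each array except that of 48 h, where it lay below it, and small differences from 0 are read against it. Markers of cell types that a fibroblast culture should lack (48 leukocyte, endothelial, keratinocyte and melanocyte genes) had a pooled median of 0.25 at 4 h, 0.24 at 16 h, -0.11 at 48 h, 0.09 at 72 h and 0.25 at 120 h. The pooled median of 159 genes of abundant transcripts (ribosomal proteins, oxidative phosphorylation and collagens) was -0.39, -0.38, 0.03, -0.26 and -0.19. The difference between both sets was 0.65, 0.62, -0.14, 0.35 and 0.43. The arrays of 4 and 16 h lacked the same 4603 of 41000 probes, against 101, 184 and 173 probes at 48, 72 and 120 h, and a processing batch cannot be told apart from early against late time.

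The first comparison asked which genes differed from uninfected cells at each time. At least 2-fold higher were 168 genes at 4 h, 151 at 16 h, 209 at 48 h, 107 at 72 h and 116 at 120 h. At least 2-fold lower were 920, 1157, 72, 227 and 676 genes. With arrays scaled to one median absolute deviation, the genes higher and lower numbered 92 and 289 at 4 h, 100 and 717 at 16 h, 462 and 254 at 48 h, and 189 and 595 at 72 h. With at least 2 probes that agree in sign, where fewer genes entered, they numbered 47 and 222 at 4 h, 31 and 295 at 16 h, 60 and 5 at 48 h, 28 and 36 at 72 h, and 37 and 195 at 120 h. With each array centred on its densest value, a setting chosen after seeing the data, they numbered 103 and 1955 at 4 h and 77 and 1133 at 120 h, and 1777 were lower at 16 h. Of the genes beyond 2-fold in the values as deposited, 84.6% were lower at 4 h, 88.5% at 16 h, 25.6% at 48 h, 68% at 72 h and 85.4% at 120 h. Centred on the densest value, 95.0% were lower at 4 h. These counts and shares rest on the likely direction of the ratio; turned, the shares lower would be 15.4%, 11.5%, 74.4%, 32% and 14.6% in the same order, and 5.0% at 4 h centred on the densest value. On all 5 arrays, 4 genes were at least 2-fold higher and 30 at least 2-fold lower. The 4 were the collagenase gene MMP1, the cell cycle gene CKS2, the hyaluronan-binding protein gene TNFAIP6 and the interleukin 13 receptor gene IL13RA2; the last was named after its values were seen.

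**Figure D1:**
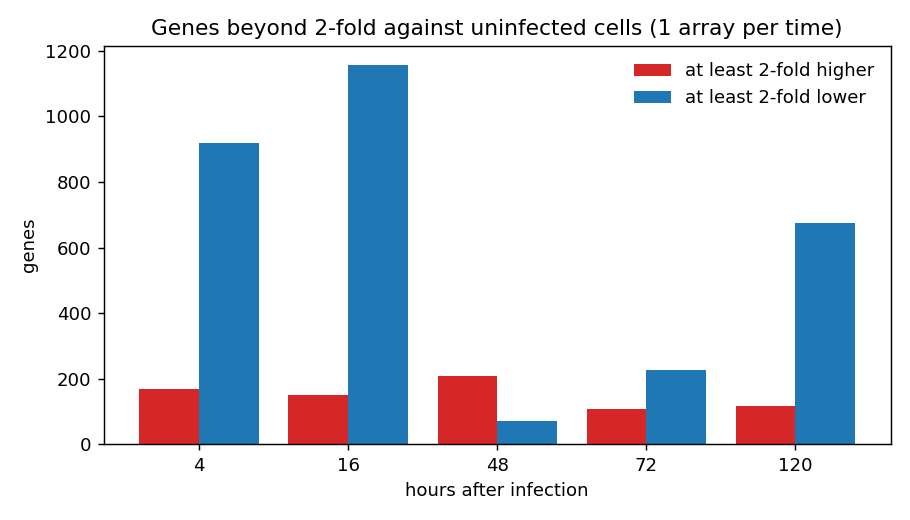
Bars give the number of genes (vertical axis) at least 2-fold higher or lower than uninfected cells of 0 h at each time after infection (horizontal axis, hours), on 1 array per time and with no error bars for lack of replicates. Lower genes outnumber higher ones at 4, 16, 72 and 120 h (920 against 168 at 4 h), and the order is turned at 48 h, with 72 against 209.

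At 4 h inflammatory genes stood out. The list of inflammatory cytokines and chemokines had a median of 1.10 over 25 genes, at percentile 100 among 10000 random lists of its size, and 13 of its genes were at least 2-fold higher. The neutrophil-attracting chemokine genes CXCL1 and CXCL2 had log2 ratios of 3.52 and 3.65, and the prostaglandin synthase gene PTGS2 had 3.90, or 14.9-fold. The highest genes were C11orf96 at 4.42, the thrombin-binding receptor gene THBD at 4.13 and the cytokine gene IL11 at 4.02. NF-kB targets and regulators had a median of 0.57, with 8 of 21 genes at least 2-fold higher, among them RELB, an NF-kB subunit, at 2.27 and CD83 at 2.12. Immediate early genes had a median of 0.35, against a densest value of 0.26 on this array. Of these 27 genes 8 were at least 2-fold higher and 3 at least 2-fold lower, with FOSB at 2.70 and EGR1 at -1.07. The heme-degrading enzyme gene HMOX1 had 2.86 and the growth factor gene HBEGF 2.69. Type I interferon-stimulated genes were not higher at 4 h, with a median of -0.23. Lowest were TXNIP, a thioredoxin inhibitor gene, at -3.12 (8.72-fold lower), HES7 at -2.81, CDC42EP5 at -2.7 and GRIN2D at -2.56. Glycolysis genes had a median of -0.63, hypoxia-induced genes -0.51, and autophagy and lysosome genes -0.51. The 159 genes of abundant transcripts named above had a pooled median of -0.39 on this array. How abundant the transcripts of these 3 lists are was not measured.

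At 16 h interferon-stimulated genes were higher and the inflammatory genes were near the level of uninfected cells. The type I interferon list had a median of 0.92, with 17 of 35 genes at least 2-fold higher. IFIT1, which binds viral RNA, had a log2 ratio of 3.98 and OASL 3.52. The inflammatory list had a median of 0.17, and CXCL1 had 0.10 and PTGS2 0.13. NF-kB targets had a median of -0.35. ID3, an inhibitor of helix-loop-helix transcription factors, had 3.05 at 4 h and 3.22 at 16 h, and the melanosome protein gene PMEL had 3.20. S phase genes had a median of 0.61, and the nucleotide salvage gene TK1 had 1.70. The metallothionein gene MT1X, which encodes a metal-binding protein, had 2.55. Lowest were ALDH1A1, a retinaldehyde dehydrogenase gene, at -4.29 (19.6-fold lower), DRICH1 at -3.69, the immediate early gene EGR1 at -3.24 and ZNF675 at -3.14. Cholesterol synthesis and uptake genes had a median of -0.86, with 8 of 20 at least 2-fold lower. The sterol enzyme gene MSMO1 had -2.58, while EBP of the same list had 0.997. The heat shock genes DNAJB1 and DNAJB4 had -2.82 and -2.56, and the signalling gene WNT5A had -2.81. The hypoxia list had a median of -0.64 and p53 targets -0.61.

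At 48 h the interferon-stimulated genes had their highest median, 2.37, and 31 of 35 were at least 2-fold higher. IFIT1 reached 5.32 (39.8-fold), IFI44L 5.11, the antiviral GTPase gene MX1 4.34 and IFI6 4.00. The RNA sensor genes IFIH1 and RIGI had 2.98 and 2.74, and IDO1, which degrades tryptophan, had 2.55. Genes of G2 and mitosis had a median of 1.13, with 25 of 39 at least 2-fold higher. The ubiquitin-conjugating enzyme gene UBE2C had 2.5, CDK1 1.76 and BUB1 1.74. S phase genes had a median of 0.53, with TK1 at 2.37, TYMS at 1.81 and RRM2 at 1.75. Replication-dependent histone genes had a median of -0.61 on the same array, with 8 of 41 at least 2-fold lower. The inflammatory list had a median of -0.04. The lowest genes were ALDH1A1 at -2.61, EGR1 at -2.14, GRIN2D at -2.10 and ZFPM1 at -1.74.

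At 72 and 120 h interferon-stimulated genes were still higher, with medians of 1.45 and 1.40. The inflammatory list had medians of 0.23 and 0.70, and 3 and 10 of its 25 genes were at least 2-fold higher. CXCL1 had 3.33 and 4.44, the latter 21.7-fold, and CXCL6 had 2.36 and 3.09. The matrix protease genes MMP1 and MMP3 had 3.27 and 2.85 at 120 h. The G2 and mitosis median was 0.94 at 72 h and 0.36 at 120 h. Cholesterol genes had a median of -0.05 at 72 h and 0.73 at 120 h, where 5 of 20 were at least 2-fold higher. None of the 4 named by the rule was among them (EBP had 0.81, MSMO1 0.67, TM7SF2 -0.41 and SREBF2 -0.47). The fatty acid list had a median of -0.07 at 120 h, although its desaturase gene SCD had 1.3. The adhesion gene CDH1, an epithelial marker, had 0.72 and 1.91, while the epithelial list as a whole had medians of 0.07 and 0.24, close to the other markers a fibroblast should lack. At 72 h GRIN2D was lowest, at -2.64, and EGR1 had -2.32. At 120 h GRIN2D had -2.57, the neural transcription factor gene PHOX2A -2.44 and INPPL1 -2.35. Within the late arrays alone, the interferon median thus went from 2.37 to 1.45 and 1.40, and within the early pair it went from -0.23 to 0.92.

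**Figure D2:**
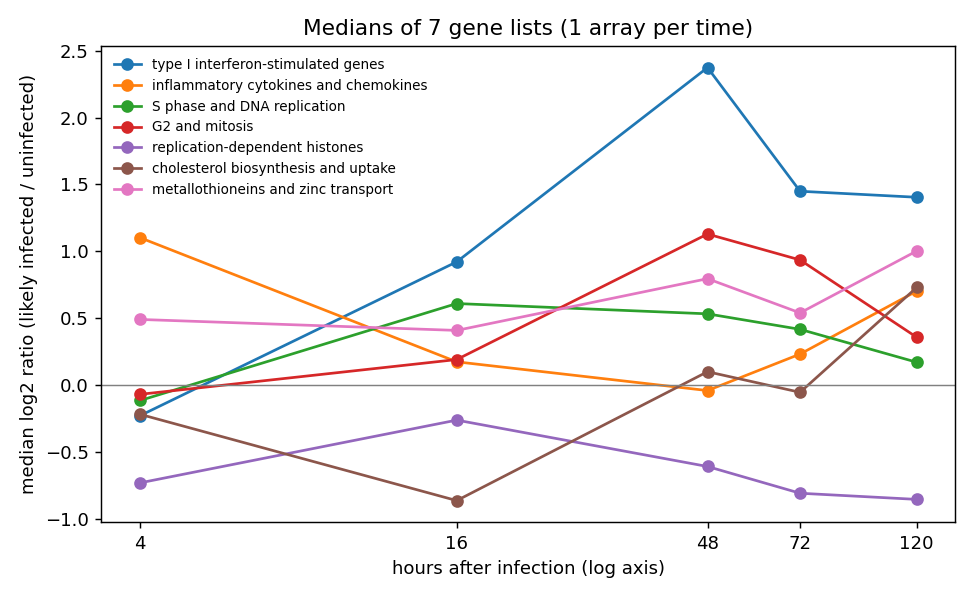
Each line gives the median log2 ratio, likely infected over uninfected (vertical axis), of the genes of 1 list at each time after infection (horizontal axis, hours, log scale), on 1 array per time and with no error bars. The interferon line is highest at 48 h (2.37), the inflammatory line is highest at 4 h (1.10), and the histone line stays below 0 at each time.

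**Figure D3:**
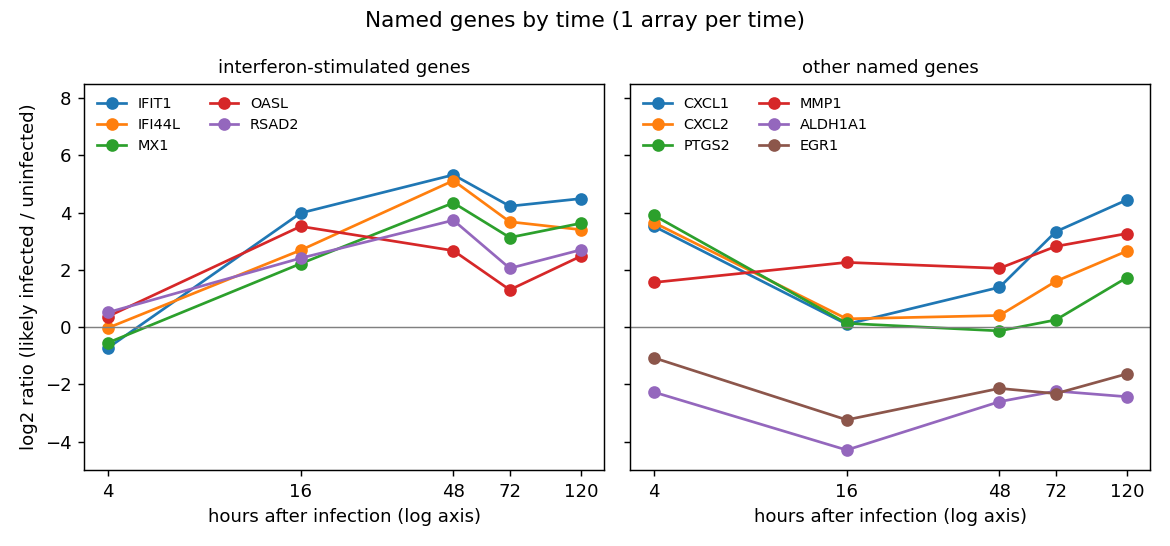
Points give log2 ratios, likely infected over uninfected (vertical axis), of single genes by hours after infection (horizontal axis, log scale), with interferon-stimulated genes in the left panel and other named genes in the right, and no error bars. IFIT1 goes from -0.73 at 4 h to 5.32 at 48 h, CXCL1 is high at 4 h (3.52) and 120 h (4.44), and ALDH1A1 and EGR1 are below 0 on each array.

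The second comparison asked which genes changed steadily with time, as a slope on log2 hours over the 5 arrays, in which the shared control and the dyes cancel. The steepest slope among the named genes was that of IFIT1, 1.04 log2 per doubling of time, and MX1 had 0.88, IFI44L 0.80 and IFI6 0.73. ID3 had -0.85, THBD -0.74 and IL11 -0.71. None of these passed the test: limma called 0 of 17074 genes (lowest adjusted p = 0.858), with 807 genes at an unadjusted p under 0.05. That number is below the share of 0.05 that genes without any trend would give. Adjusted over the list alone, 21 of the 35 type I interferon genes rose. Leaving out the 4 h array gave 71 genes and leaving out the 16 h array 13. Among the 2513 genes beyond 2-fold on at least 1 array, 24 passed, 15 rising and 9 falling. Of the rising ones, 11 were in the interferon list. That filter picks genes by their own size. Among the 24, the adjusted p followed the order of slope size, so passing acted as a cut on slope. IFIT1, at the same slope, had an adjusted p of 4.64e-08 by limma after the filter, against 0.858 over all genes. THBD passed with 4.13 at 4 h and at most 0.446 later, which is no steady change.

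Of the 41 gene lists, 17 had a time trend by camera, 13 upward and 4 downward relative to the other genes, and none with an estimated correlation (lowest adjusted p = 0.672). The type I interferon list rose (adjusted p = 2.37e-26; adjusted p = 0.672 with an estimated correlation), as did G2 and mitosis (adjusted p = 1.15e-13; adjusted p = 0.672 with an estimated correlation). Hypoxia-induced genes rose from their low medians at 4 and 16 h (adjusted p = 1.00e-06; adjusted p = 0.672 with an estimated correlation), as did cholesterol genes (adjusted p = 5.41e-05; adjusted p = 0.672 with an estimated correlation). Ribosomal protein genes rose relative to other genes (adjusted p = 2.13e-05; adjusted p = 0.728 with an estimated correlation), as did the autophagy and lysosome list (adjusted p = 2.35e-05; adjusted p = 0.728 with an estimated correlation), and the gap between markers a fibroblast should lack and abundant genes moved over the same arrays. Without the 4 h array both of these calls ended (adjusted p = 0.0806 and adjusted p = 0.722), and of the 17 lists 5 kept their call and direction, namely type I interferon, G2 and mitosis, hypoxia, cholesterol and histones. The cholesterol call ended without 120 h (adjusted p = 0.06005), and the histone call ended without 16 h (adjusted p = 0.682), 48 h (adjusted p = 0.117), 72 h (adjusted p = 0.189) or 120 h (adjusted p = 0.506). Without 48 h the calls of immediate early genes, collagens and TGF-beta targets ended (adjusted p = 0.0846, adjusted p = 0.0961 and adjusted p = 0.0694), as did that of TGF-beta targets without 120 h (adjusted p = 0.0598). The type I interferon, G2 and mitosis, and hypoxia lists were the 3 whose trend call was kept with each array left out in turn. Immediate early genes fell (adjusted p = 0.00970; adjusted p = 0.785 with an estimated correlation), and without the 4 h array the list rose instead (adjusted p = 0.000193). The S phase list rose (adjusted p = 0.000629; adjusted p = 0.785 with an estimated correlation) and without the 4 h array it fell (adjusted p = 0.000874). Upward calls were also made for glycolysis, oxidative phosphorylation, fibroblast markers, the interferon gamma list, collagens and the reference genes, and downward calls for growth factors, TGF-beta targets and histones, with an adjusted p from 0.672 to 0.785 with an estimated correlation. With early and late arrays as batches, added after seeing the data, 8 lists were called, 3 of them as before. The calls of the interferon list (adjusted p = 0.0512) and of G2 and mitosis (adjusted p = 0.157) ended. So did those of the hypoxia (adjusted p = 0.0789) and cholesterol lists (adjusted p = 0.211), and the histone list turned direction (adjusted p = 0.00115).

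The third comparison asked which genes differed from uninfected cells on average over the 5 arrays, taking each time point as 1 infected sample. MMP1 was higher at a mean log2 ratio of 2.39 ± 0.67 (SD over 5 time points; adjusted p = 0.00306), with the same sign on 5 of 5 arrays, and CKS2 at 1.75 ± 0.16 (adjusted p = 0.000640). CXCL1, with 2.56 ± 1.77, and IFIT1, with 3.45 ± 2.39, varied far more. Other genes with the highest means and the same sign on each array were RSAD2 (2.28), TNFAIP6 (2.11), OASL (2.07), PMEL (1.87), OAS1 (1.82), TFPI2 (1.77) and CXCL2 (1.72). On the lower side were ALDH1A1 at -2.77 ± 0.87 (adjusted p = 0.00395), GRIN2D at -2.36 ± 0.32 (adjusted p = 0.000683), EGR1 at -2.08, ZFPM1 at -2.04, LIMS2 at -1.96, HES7 at -1.93, PHOX2A at -1.82, ADGRB2 at -1.81, LCE5A at -1.78 and the matrix enzyme gene LOXL4 at -1.69. GRIN2D, HES7, PHOX2A and LCE5A are best known from neurons, embryonic somites and skin epithelium, and each of these lower genes except LOXL4 was measured by 1 probe. By limma, 2736 of 17074 genes were called, 887 higher and 1849 lower, of which 50 and 187 were at least 2-fold. With each array centred on its densest value, chosen after seeing the data, 377 were higher and 1685 lower, of which 14 and 299 were at least 2-fold. Without the 48 h array 2696 were higher and 2767 lower, or 5463 in all. The count was 1155 without the 4 h array, 590 without 72 h and 845 without 120 h, and 1033 among genes with at least 2 probes. Called genes at least 2-fold higher ranged from 22 (without 120 h) to 61 (without 4 h). Those at least 2-fold lower ranged from 145 (without 4 h) to 302 (without 48 h). The p-values measure the spread between time points and leave out that of the control and any dye effect of a gene.

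Camera called 16 lists on the mean, 6 higher and 10 lower, and none with an estimated correlation (lowest adjusted p = 0.407). With each array centred on its densest value, the 6 higher calls and 5 of the 10 lower calls were kept, and melanocyte markers were called higher as well. In the type I interferon list 20 of 35 genes were higher, 26 adjusted over the list alone, and 15 did not pass (list adjusted p = 3.48e-10, adjusted p = 0.657 with an estimated correlation). Of the inflammatory genes 6 of 25 were higher, 8 adjusted over the list alone, among them CXCL1, CXCL2 and CXCL6 (list adjusted p = 0.000182, adjusted p = 0.696 with an estimated correlation). In G2 and mitosis 10 of 39 were higher, 16 adjusted over the list alone, with CKS2, CDK1 and BUB1 among them (list adjusted p = 1.21e-09, adjusted p = 0.657 with an estimated correlation). In S phase 9 of 36 were higher, 13 adjusted over the list alone, with TK1 and RRM2 (list adjusted p = 2.00e-06, adjusted p = 0.657 with an estimated correlation). Metallothioneins and zinc transport had 9 of 15 genes higher, also 9 adjusted over the list alone, with MT1H at a mean of 1.40, MT1X at 1.40 and MT1G at 1.19 (list adjusted p = 0.000107; adjusted p = 0.407 with an estimated correlation); these genes are near-identical in sequence and their probes may not tell them apart. Its median was above 0 on each array, from 0.41 to 1.00.

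Among the lower lists, 26 of 41 replication-dependent histone genes were lower and 1 was higher, with 28 lower adjusted over the list alone. H2BC9 had a mean of -1.66, H2BC17 -1.54, H2BC3 -1.42 and H2AC7 -1.40 (list adjusted p = 3.48e-10, adjusted p = 0.657 with an estimated correlation). Most histone messages lack a poly(A) tail while the cDNA was primed with oligo-dT, and histone copies share sequence. TGF-beta targets and contractile genes had 9 of 27 lower, 12 adjusted over the list alone, including TGFB1 at -1.34, LMOD1 at -1.39 and CCN2 at -0.96 (list adjusted p = 0.00888, adjusted p = 0.657 with an estimated correlation). In this list 1 gene was higher, 3 adjusted over the list alone. ID3, also named from it, went the other way with a mean of 1.23, which did not pass. Actin cytoskeleton and adhesion genes had 8 of 32 lower, 11 adjusted over the list alone, with ITGA5 at -1.38 and ZYX at -1.37 (list adjusted p = 0.00126; adjusted p = 0.657 with an estimated correlation). The NRF2 list had 9 of 30 lower, 12 adjusted over the list alone, with GPX4 at -1.19 and NQO1 at -0.78 (list adjusted p = 0.00443, adjusted p = 0.657 with an estimated correlation). In it 1 gene was higher. HMOX1, also named from this list, went the other way with a mean of 0.75, which did not pass. Ribosomal proteins had 13 of 53 lower, 21 adjusted over the list alone (list adjusted p = 1.84e-06; adjusted p = 0.657 with an estimated correlation), oxidative phosphorylation 7 of 61, 6 adjusted over the list alone (list adjusted p = 0.000307; adjusted p = 0.714 with an estimated correlation), and collagens 11 of 45, 15 adjusted over the list alone (list adjusted p = 0.0138; adjusted p = 0.696 with an estimated correlation). The calls of the TGF-beta and collagen lists ended with arrays centred on the densest value (adjusted p = 0.110 and adjusted p = 0.144). So did those of the autophagy and lysosome, p53 target and proteasome lists, which were called lower too, with 6 of 38, 5 of 20 and 0 of 26 genes lower (adjusted p = 0.718, adjusted p = 0.657 and adjusted p = 0.718 with an estimated correlation). Without the 4 h array the mean calls of collagens (adjusted p = 0.0502), the autophagy and lysosome list and the proteasome (adjusted p = 0.0549 each) ended, and that of the proteasome ended also without 16 h (adjusted p = 0.137) or 72 h (adjusted p = 0.0575). Over the 5 arrays the leukocyte markers were called higher (adjusted p = 0.0201; adjusted p = 0.714 with an estimated correlation), a call that ended without 16 h (adjusted p = 0.0705) or 120 h (adjusted p = 0.0550), with CD163 at a mean of 0.43 and ITGAM at 0.41. In the values as deposited the epithelial, keratinocyte, endothelial and melanocyte lists were not called, apart from PMEL no marker among them was 2-fold higher before 120 h, and the melanocyte gene MLANA had a mean of 0.25.

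The time points were also compared with each other across genes, which are not independent replicates. By Pearson the highest correlation was between 72 and 120 h (Pearson r = 0.752, Spearman rho = 0.713), followed by 4 and 120 h (r = 0.692, rho = 0.724). By Spearman the order of these 2 pairs was turned. The 48 h array was closest to 72 h (r = 0.655) and far from 4 h (r = 0.182) and 16 h (r = 0.163). The mean over 10 pairs was 0.485, and unchanged RNAs against 1 shared control gave 0.504 in a simulation. The mean covariance was 0.0952, against 0.103 from a shared control alone if all variance were noise split equally between channels. Single pairs lay on both sides of their own such value, with 0.167 against 0.121 for 4 and 120 h, 0.122 against 0.0814 for 72 and 120 h, 0.0789 against 0.0602 for 48 and 72 h, and 0.0302 against 0.0928 for 16 and 48 h. Part of any excess may come from the shared control, which could not be split. Between 48 and 72 h, 88 genes were at least 2-fold higher on both arrays and 66 at least 2-fold lower on both. Independent lists give 1.19 and 0.923, and lists of the same lengths that share only a control gave at most 51 and 39 in 100 simulations with each gene's own spread. For 4 and 16 h, 27 higher and 274 lower genes were shared, against means of 46.2 and 396.3 in those simulations, so that this overlap was no larger than the shared control gave. Steps that share no array, such as 4 to 16 h and 72 to 120 h, had correlations from -0.300 to -0.121.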

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

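The tests on signal level and shared processing for the lower genes, and on shared processing for the interferon genes, were chosen only after the result was seen.

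Several lists lay outside the central 95% of random lists on opposite sides at different times, on 1 array each. These differences between time points were not tested. Positions outside that range were common on every array. Above and below it lay 8 and 12 lists at 4 h, 6 and 14 at 16 h, and 15 and 4 at 48 h. At 72 h they numbered 7 and 12, and at 120 h 12 and 10. Lying outside the range therefore does not by itself set a list apart. NF-kB targets had a median of 0.57 at 4 h and -0.35 at 16 h, and immediate early genes 0.35 and -0.40. Cholesterol genes had -0.86 at 16 h and 0.73 at 120 h. The autophagy and lysosome list had -0.51 at 4 h and 0.16 at 48 h, oxidative phosphorylation -0.39 and 0.063, and the proteasome -0.34 and 0.18. The ATF4 list had 0.15 at 48 h and -0.24 at 72 h.

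Among the 11668 probes with no listed gene, 8 were at least 2-fold higher and 13 at least 2-fold lower on all 5 arrays, a signal outside the comparisons by gene. Over all unlisted probes, the 2 with the highest means were A_24_P920715, with log2 ratios of 1.15, 2.37, 3.07, 4.67 and 5.46 from 4 to 120 h, and A_23_P126706, with 0.43, 0.15, 1.97, 3.47 and 3.93. Among the lower ones A_24_P780709 had a mean of -2.01 and A_23_P217326 of -1.995.

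More genes were lower than higher at 4, 16, 72 and 120 h but not at 48 h. Processing shared by the 4 and 16 h arrays would not cover the 120 h array, which had 9.39 times as many genes at least 2-fold lower as the 48 h array. That count is part of the pattern itself and so is no separate test. A share of such processing at 4 and 16 h stays open. A dependence on signal level may contribute: markers that fibroblasts should lack exceeded abundant genes by at least 0.352 on each of the 4 arrays, against -0.14 at 48 h. Base composition stays open, because a gene's correlation with its neighbours was 0.134 on the mean of the 4 arrays (highest of 20 shuffled orders 0.022), between the bounds set for it, and 0.082 at 48 h (highest 0.013). On single arrays the correlation was 0.135 at 4 h, 0.038 at 16 h, 0.145 at 72 h and 0.232 at 120 h. At 16 h, where the most genes were lower, it thus lay below that at 48 h. The infection itself stays open too, untested in a design without replicates or uninfected cells of the same age.

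Type I interferon-stimulated genes were higher from 16 h on, with the highest median at 48 h. Processing shared by the 4 and 16 h arrays would not cover the difference of 1.15 between the medians of these 2 arrays. That difference is part of the pattern itself and so is no separate test. For RNA of the dog kidney cells, epithelial markers were compared at 48 h only. They lay at -0.046 relative to the other markers fibroblasts should lack, and so gave no sign of such RNA. Whether dog transcripts bind these human probes was not measured, so the test cannot exclude it. A signal-level effect is argued against at 48 h, where the median was 17.0 times the size of the signal-level difference. No such ratio was formed on the other arrays. The median and the difference were 0.92 and 0.62 at 16 h, 1.45 and 0.35 at 72 h, and 1.40 and 0.43 at 120 h. Signal level therefore stays open for the onset at 16 h. A response to infection stays a hypothesis, found and tested on the same data; time in culture, and interferon made by the MDCK cells and carried over with the spores, were not tested.

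S phase and mitosis genes were higher at 48 and 72 h while replication-dependent histone genes were lower, with a histone median of -0.61 at 48 h. Base composition cannot be told apart from the other explanations, because the neighbour correlation at 48 h was 0.612 of that on the other arrays, between the bounds set for it. Time in culture or a change of medium cannot be told apart from infection, because 0 uninfected arrays follow 0 h. The labels describe the cells as confluent at infection, so growth of the culture remains open too.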

How the results depend on the processing

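Centring on the densest value, the late arrays alone and the batch block were chosen after seeing the data. With arrays scaled to one median absolute deviation, genes at least 2-fold higher and lower numbered 92 and 289 at 4 h, 100 and 717 at 16 h, 462 and 254 at 48 h, and 189 and 595 at 72 h. With at least 2 probes that agree in sign they numbered 47 and 222 at 4 h, 31 and 295 at 16 h, 60 and 5 at 48 h, 28 and 36 at 72 h, and 37 and 195 at 120 h, where fewer genes entered. Centred on the densest value they numbered 103 and 1955 at 4 h, 77 and 1133 at 120 h, and 1777 were lower at 16 h. Centring on the median and the median of probes moved none of these counts by over 1.5 times.

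Genes with a time trend numbered 0 to 71 over the fits without 1 array, 24 after the filter on size, and 2 for late against early arrays (ID1 and PTMS, named after their values were seen); centring, scaling, quantile normalization, the median of probes, robust eBayes, the other codings of time and the batch block gave 0. Genes changed on average numbered 590 to 5463 over the fits without 1 array and 1033 with at least 2 probes. The late arrays alone gave 2193, of which 354 higher and 1264 lower genes were also called over the 5 arrays.

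Lists with a time trend numbered 11 to 22 without 1 array (without 4 h, 5 of the 17 calls were kept, 10 ended and 2 turned, and 3 were kept in each of these fits), 9 with time as hours, 8 with the batch block, and 0 with an estimated correlation or fry. Without 4 h, immediate early genes (adjusted p = 0.000193) and the list of S phase and DNA replication (adjusted p = 0.000874) turned direction, and with the batch block histones did (adjusted p = 0.00115); the cause was not tested. Without 1 array the adjusted p of both lists ranged from 9.58e-08 to 0.0846 and from 4.90e-09 to 0.00384. Lists changed on average numbered 14 to 18 without 1 array (12 of the 16 calls were kept in each), 12 centred on the densest value, 0 with an estimated correlation, and 4 by fry, which does not compare lists with other genes (metallothioneins at an adjusted p of 0.00654, histones, pattern recognition receptors and TGF-beta targets). Single lists gave 969 values on the same side as before, 134 lost, 42 gained and 3 turned, and named genes 2202, 232, 83 and none. Robust eBayes was not run for lists, because camera does not take it. No paired analysis was possible because each group holds 1 sample. Spot signal over background was not analysed here.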

Other observations

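No test in this part was planned beyond the filter on size, and genes here were named after their values were seen.

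Among the genes beyond 2-fold on at least 1 array, 9 had a falling slope that passed after the filter. Over all 17074 genes limma called none (lowest adjusted p = 0.858). The 9 had different time courses. ID1, an inhibitor of helix-loop-helix transcription factors like ID3, had log2 ratios of 2.61 at 4 h, 3.06 at 16 h and -0.57 at 48 h (adjusted p = 2.31e-05 after the filter), and the alarmin gene IL33 had 3.00, 2.70 and -0.42. THBD, IL11, the growth factor gene EREG and the lipase inhibitor gene ANGPTL4 were high at 4 h alone among the early arrays, with EREG at 3.32 and then -0.75, and ANGPTL4 at 3.08 and then -0.12. DIRAS3 had 2.87 and 0.97. Of the 15 rising genes, 4 were not in the type I interferon list. The matrix protease gene MMP3 reached 2.85 at 120 h, the securin gene PTTG1 had -1.38 at 16 h and 1.80 at 48 h, and PDP1 had -2.05 and 0.79. The fourth, PLSCR1, is named with the antiviral genes that follow. The antiviral genes IFITM1, PLSCR1 and SAMD9L had 0.10, -0.42 and -0.57 at 16 h, when IFIT1 already had 3.98, and 2.49, 2.44 and 2.37 at 48 h.

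PMEL was the melanocyte marker that stood apart, with 2.60, 3.20, 2.57, 0.31 and 0.65 from 4 to 120 h on 2 probes. S100B had a mean of 0.35, MLANA 0.25 and MITF -0.41. In all, 45 genes were at least 2-fold higher at 1 time and at least 2-fold lower at another.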
